A study of Mus musculus with 41 samples.

How the data were processed

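Single cells of hippocampus and frontal cortex, taken on the injured side, were profiled with Drop-seq in male C57BL/6J mice 10 weeks old. The mice received a fluid percussion injury of 1.5 to 1.7 atm, followed by intraperitoneal thyroxine (T4, 1.2 µg per 100 g) or saline at 1 h and 6 h, or a sham operation. The 41 libraries form 14 groups: T4 and TBI (injury with saline) at 24 h, 7 d and 21 d in both tissues, and sham at 21 d. Every group had 3 libraries except cortex T4 at 21 d, which had 2, numbered 2 and 3. Per the labels 7 mice per group were operated on and 3 sequenced. Sham mice at 24 h and 7 d were not analysed here. Cells had been freed with papain and cleaned on an OptiPrep density gradient, a treatment that keeps cell types unequally, so shares of cells describe the suspensions and not the tissue. Numbers 1 to 3 are those of the labels. The labels gave no sequencing date or batch.

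The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, all whole numbers. According to the submitters' notes, reads were demultiplexed with bcl2fastq and aligned with STAR 2.5.0c to mm10 (GRCm38), and the notes also mention Cell Ranger. The matrices of 39 libraries start at 20 detected genes per barcode. Those of cortex TBI number 1 and of the sham library labelled cortex number 3, both at 21 d, start at 100 genes. These 2 also list fewer genes (19360 and 19612, against 20663 to 22994), and 470 of the 16911 genes listed in every other library are in neither of them. Their genes with long introns are low: Spearman's rho of intron length with the log2 difference from the other 21 d libraries is −0.414 and −0.486, against −0.279 to 0.250 elsewhere. The tenth of genes with the longest introns lies at a median of −0.89 and −0.90, against −0.61 to 0.32 elsewhere.

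Barcodes with at least 200 detected genes and at most 20% of UMIs from mitochondrially encoded genes were kept as cells. This left 135741 of 316474 barcodes and 182323750 of 204897759 UMIs, with 1568 to 5657 cells per library, a median of 448.5 to 1233 UMIs per cell and 318.5 to 812 genes per cell. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 40 principal components, and a graph of 15 neighbours was clustered with the Leiden method (resolution 1) within each time point (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). A cluster was named when at least 3 markers of a class, each detected in 10% of its cells, stood among its 30 leading genes (fold of at least 1.5 after adding 50 CPM) and the class led the next by 2.5 times. A cluster also stayed unnamed when 25% of its cells were called doublets, or when its 10 leading genes held more markers of another class. The marker lists were written before the data were examined, and these naming thresholds were set after the clusters had been seen. Of 81 clusters 24 stayed unnamed, holding 10.1% of cells at 24 h, 9.82% at 7 d and 8.14% at 21 d. The unnamed share averaged 9.73% (T4) and 9.80% (TBI) in cortex at 24 h, 9.94% and 11.3% in hippocampus at 24 h, 9.65% and 11.2% in cortex at 7 d, and 11.9% and 7.48% in hippocampus at 7 d. At 21 d it averaged 5.66% (T4), 6.54% (TBI) and 10.2% (sham) in cortex, and 8.77%, 8.04% and 7.80% in hippocampus as labelled. In all 14 of 16 classes were found. Scrublet, run per library, called 1914 doublets (1.38% of cells, 0.133% to 4.22% per library, and under 0.5% in 6 libraries, where it can be taken not to have worked). They were kept, and left out as an alternative.

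UMIs were summed per library and class wherever a library had at least 20 cells of the class, so that the library, and not the cell, was the unit of replication. Genes passing filterByExpr were tested with edgeR 4.0.16 (TMM normalization, quasi-likelihood F test; R 4.3.3). Benjamini-Hochberg adjustment ran over all gene and class pairs of a comparison, with a threshold of 0.05; a pair past it is called. Levels are mean CPM (counts per 1000000) ± SD over libraries, and folds are log2 with a standard error (SE). Gene lists with at least 5 tested members were tested per class with camera (limma 3.58.1) at its preset correlation between genes of 0.01, and again with a correlation estimated from the libraries. Of 23 lists, 21 were tested between groups and 2, of hippocampal and of neocortical neuron markers, served to check the tissue. Shares of classes were compared by exact permutation, where the smallest possible p is 0.10 for 3 against 3 libraries and 0.20 for 2 against 3. Groups, comparisons, lists and alternatives were fixed before the data were examined, except for 5 alternatives chosen after the data had been seen: leaving out the 2 libraries with shorter gene lists, leaving out 42 choroid-enriched genes, tissue as a covariate with the sham tissues exchanged, a block for the tissue differences, and shares in cortex at 24 h without inhibitory neurons.

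The comparisons were T4 against TBI in each tissue at each time, TBI against sham and T4 against sham at 21 d, the difference of the T4 effect between tissues at each time, and its difference between 24 h and 7 d in each tissue. For sham numbers 2 and 3 the deposited labels and file names give opposite tissues. Sham comparisons were therefore led by the sum of both tissues per number, which is the same whichever tissue label holds. The mix of tissues in a sum still varied. Sham number 2 summed 5394 cells labelled cortex and 2354 labelled hippocampus, and TBI number 2 summed 4693 and 3745. The comparisons by tissue follow the labels. One hippocampal T4 library at 21 d (number 1) has a characteristic reading TBI and a title reading T4, and was used as T4. The labels do not say whether a number marks 1 mouse across tissues. Same-numbered libraries correlated above 0.1 for every number, with 3 numbers shared, in 2 of 17 pairs of groups. These were T4 of cortex and hippocampus at 24 h (0.126 to 0.345, against −0.287 to −0.008 for different numbers), and sham and TBI of hippocampus at 21 d as labelled (0.152 to 0.284), which come from different mice. T4 and TBI of cortex at 21 d, sharing numbers 2 and 3 alone, also lay above 0.1 (0.191 and 0.161). Numbers entered the model as an alternative, as a block. No 2 libraries of a group were copies (lowest chi-square per degree of freedom 4.46 over 40 pairs, correlations of log2 CPM 0.775 to 0.984).

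The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no low-count filter, at least 400 genes per cell, no mitochondrial limit, doublets left out, Leiden resolution 2, at least 50 cells of a class, adjustment within each class, all cells of a library summed, the number as a block, each library left out in turn, spread shared by all 3 groups at 21 d, tissue as a covariate, the sham tissues exchanged, and T4 number 1 counted as TBI. Tested on simulated data with 200 changed genes, the pipeline recovered 16.9% to 40.0% of genes changed 2-fold and 80.2% to 95.2% of those changed 4-fold in comparisons of 3 against 3 libraries, other than TBI against sham in cortex (0% and 44.7%). For cortex T4 against TBI at 21 d, with 2 against 3 libraries, recovery was 1.06% and 37.4%. For T4 against sham it was 22.9% and 75.0%, and for differences between effects at most 6.19% and 28.6% to 52.0%. Unchanged pairs made up over 5% of the simulated calls in each of the 15 comparisons, more than the threshold aims at. T4 against TBI had 8 of 118 false in cortex and 8 of 106 in hippocampus at 24 h, 9 of 100 and 8 of 121 at 7 d, and 22 of 57 (38.6%) and 11 of 122 at 21 d. TBI against sham had 8 of 46 in cortex and 8 of 108 in hippocampus as labelled and 15 of 123 with both tissues, and T4 against sham 18 of 112. The tissue differences had 4 of 61, 5 of 48 and 7 of 36 at 24 h, 7 d and 21 d, and the time differences 4 of 48 in cortex and 7 of 47 in hippocampus. Small changes were therefore mostly out of reach, and a gene that was not called cannot be taken as unchanged.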

Results

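Droplet counts of single cells were compared between mice given thyroxine (T4) after a fluid percussion injury, injured mice given saline (TBI) and sham mice, to ask which genes differ with T4 in each cell class of hippocampus and frontal cortex. The 41 libraries held 135741 cells, 1568 to 5657 per library, at a median of 448.5 to 1233 UMIs per cell. Groups had n = 3 libraries except cortex T4 at 21 d with n = 2, and sham was available at 21 d. Clusters gave 14 classes, among them astrocytes, microglia, oligodendrocytes and their precursors, endothelial and mural cells, excitatory, inhibitory and immature neurons, ependymal, choroid plexus-like and fibroblast-like cells. A class name stands for cells that resemble the class by their markers. UMIs were summed per library and class, and each gene and class pair was tested with edgeR.

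The tissue of 4 sham libraries at 21 d, numbers 2 and 3, differs between their labels and their file names, and marker genes were read in each. C1ql2, a gene of hippocampal granule cells, stood at 12.7 and 18.2 CPM in sham libraries 2 and 3 labelled cortex and at 1.91 and 1.56 CPM in those labelled hippocampus. Markers of neocortical projection neurons summed to 313 and 213 CPM in the former and 704 and 446 CPM in the latter. Ttr, the thyroid hormone carrier made by choroid plexus, took 103467 and 109395 CPM in the former and 86.1 and 0.991 CPM in the latter. Choroid plexus-like cells numbered 250 and 164 in the former and 0 and 0 in the latter. A score from 30 genes per tissue, chosen at 24 h and 7 d, put 13 of the 13 other libraries of 21 d on the side of their label, with hippocampus at −0.704 to 1.22, cortex at −2.80 to −1.32 and the midpoint at −0.720, close to the lowest hippocampal library. The libraries labelled cortex scored 0.566 and 0.789, and those labelled hippocampus −3.42 and −2.08, so that 4 of 4 lay on the other side. Sham was therefore compared first with both tissues summed per number, and then by labelled tissue.

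**Figure D1:**
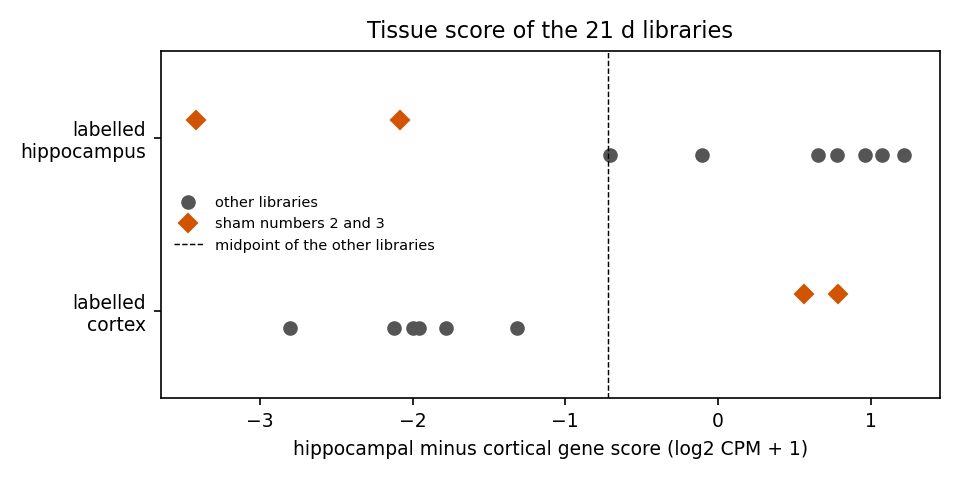
Hippocampal minus cortical score of each library at 21 d, from genes chosen at 24 h and 7 d. Sham libraries 2 and 3 are placed under their labelled tissue.

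In cortex at 24 h, endothelial cells differed most between T4 and TBI. Vwf, which encodes the von Willebrand factor that endothelium releases when activated, stood at 572 ± 177 CPM with T4 and 198 ± 59.6 CPM with TBI (log2 fold 1.54, SE 0.23, adjusted p = 0.00605, n = 3 each). Il1r1, the receptor through which interleukin 1 reaches endothelium, stood at 256 ± 56.6 and 81.0 ± 30.1 CPM (1.69, SE 0.25, adjusted p = 0.00605), and the scaffold gene Akap12 at 642 ± 106 and 233 ± 25.1 CPM (1.48, SE 0.18, adjusted p = 0.000726). Each of these 3 genes was higher in every T4 library than in any TBI library. Cav2, a caveolin, was lower in T4 endothelium (72.9 ± 12.2 against 181 ± 14.9 CPM, log2 fold −1.32, SE 0.23, adjusted p = 0.0356). Islr was lower in T4 astrocytes (11.2 ± 9.67 against 117 ± 58.2 CPM, −3.15, SE 0.49, adjusted p = 0.0256). The endothelial activation genes had a median log2 fold of 1.50 over 9 members, 8 higher and 1 lower, of which 2 passed over all genes and 8 when adjusted over the list alone. Camera called the list, and the call was lost with an estimated correlation (adjusted p = 0.316). Its other members with high folds were Lrg1 (1.94, SE 0.41), Ch25h (1.70), Lcn2 (1.50, SE 0.37), Sele (1.33), Icam1 (1.05, SE 0.30) and Vcam1 (0.90, SE 0.20), none past the threshold over all genes, with Edn1 at −0.56. In astrocytes the mitochondrially encoded transcripts had a median of −0.50, and in microglia the homeostatic genes had one of −0.21 over 14 members (adjusted p = 0.923 for both with an estimated correlation). Blood-brain barrier genes had a median of −0.10, not called with an estimated correlation. Apoe in microglia had a log2 fold of −1.32 (SE 0.36, adjusted p = 0.400).

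Over all classes 5 of 39606 gene and class pairs were called in cortex at 24 h, 3 higher and 2 lower, with 2363 at an unadjusted p under 0.05, and DESeq2 called 30. Camera called 20 of 91 lists, none with an estimated correlation. The count was 144 without T4 number 1, 31 without T4 number 2, 20 without T4 number 3, 13 without TBI number 2 and 18 without TBI number 3. It was 0 when all cells of a library were summed. Vwf and Akap12 were called under every setting, Il1r1 under all but Leiden resolution 2 (1.50). Cav2 lost its call without T4 number 3 (−1.26) or without TBI number 1, 2 or 3 (−1.30, −1.38 and −1.25) or at Leiden resolution 2 (−1.29), and Islr without T4 number 3 (−2.87) or TBI number 1 (−2.98) or with at least 400 genes per cell (−3.01).

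**Figure D2:**
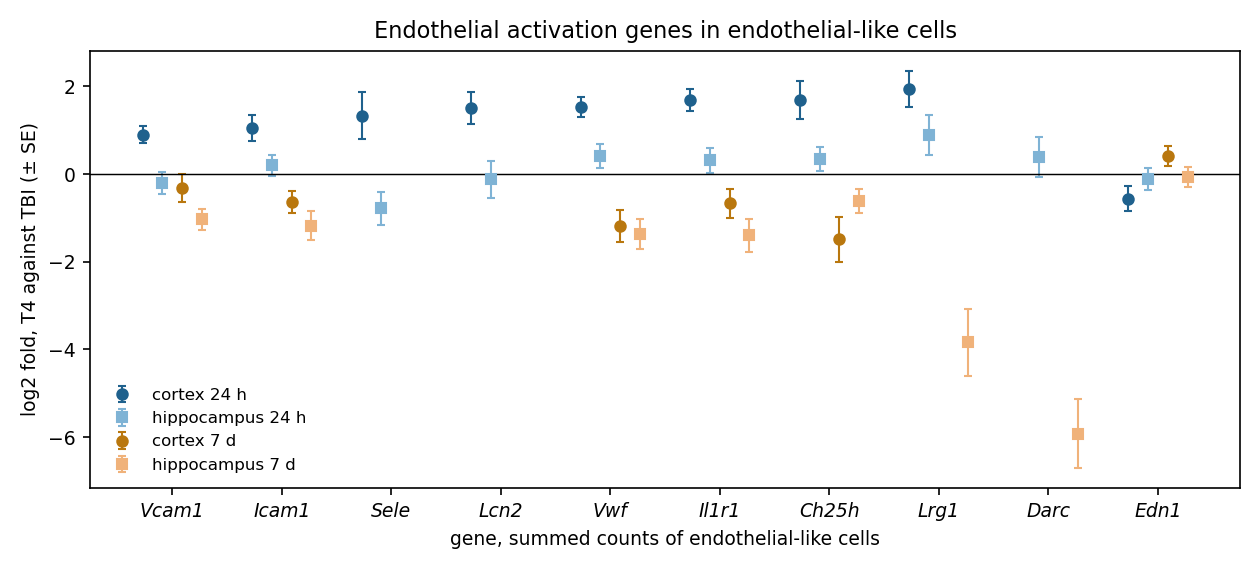
Log2 folds, T4 against TBI, of endothelial activation genes and of Darc, tested outside the list, in endothelial cells, with SE, at 24 h and 7 d. Vwf and Il1r1 in cortex at 24 h and Darc in hippocampus at 7 d passed the threshold over all gene and class pairs.

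Hippocampus at 24 h showed no called pair. Gfap, the intermediate filament of reactive astrocytes, averaged 2450 ± 379 CPM with T4 and 3988 ± 656 CPM with TBI in astrocytes (log2 fold −0.68, SE 0.20, adjusted p = 1.00, n = 3 each). The reactive astrocyte genes had a median of −0.47, with 16 of 19 members lower and 4 lower when adjusted over the list alone, a camera call lost with an estimated correlation (adjusted p = 0.720). Mitochondrially encoded transcripts had positive medians in mural cells (0.60), oligodendrocyte precursors (0.53), microglia (0.46) and oligodendrocytes (0.42), also called at the preset correlation and not with the estimated one (adjusted p = 0.720). In endothelial cells the activation genes went both ways, from −0.78 (Sele) to 0.89 (Lrg1), with Vwf at 0.41 and Vcam1 at −0.20, and none was called. edgeR called 0 of 38972 pairs, with 1531 at an unadjusted p under 0.05, and DESeq2 called 5. Camera called 23 of 88 lists and 0 with an estimated correlation. Without TBI number 2 the count was 46, without TBI number 1 it was 4 and without T4 number 2 it was 2. The difference between the T4 effects in cortex and hippocampus at 24 h was called for 0 of 39468 pairs by edgeR, with 1521 at an unadjusted p under 0.05, and for 0 by DESeq2. It was called for 5 without cortex T4 number 2, 2 without cortex TBI number 3 and 1 without cortex T4 number 1. With group and number as a block, chosen after the data had been seen, 6 were called. Of these, 5 were in astrocytes (Fabp7 −2.02, Nupr1 2.31, Hspb1 3.58, Tagln2 2.74 and 6330403K07Rik −2.78) and 1, Apod, in excitatory neurons (−3.79). The endothelial genes were not called with or without the block, and so were not shown to differ between tissues. Their list had a median difference of 1.13 (adjusted p = 0.346 with an estimated correlation).

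In cortex at 7 d, 3 pairs were called, all higher with T4. Adarb2, an RNA editing enzyme homologue found in subsets of neurons, stood at 547 ± 294 CPM with T4 and 85.3 ± 28.3 CPM with TBI in excitatory neurons (log2 fold 2.70, SE 0.34, adjusted p = 0.000202, n = 3 each). The T4 libraries held 227 excitatory and 676 inhibitory neurons, and the TBI libraries 500 and 378. Whether RNA or cells of inhibitory neurons entered the sums of excitatory neurons was not tested. Gria1, a glutamate receptor subunit, stood at 219 ± 56.1 and 49.8 ± 13.02 CPM in astrocytes (2.19, SE 0.30, adjusted p = 0.000762). Usp24, a ubiquitin protease, stood at 402 ± 376 and 30.6 ± 12.2 CPM in endothelial cells (3.81, SE 0.58, adjusted p = 0.0124). Usp24 was also abundant outside cells in these libraries, at 8251, 10516 and 79.9 CPM in cortex T4 barcodes with under 200 genes. Glycolysis genes had negative medians in 7 classes, from −0.67 in microglia and −0.63 in endothelial cells (4 members lower when adjusted over the list alone) to −0.32 in astrocytes. Microglia had lower medians for disease-associated genes (−0.33, 14 of 14 lower) and for cytokines and chemokines (−0.41, 14 of 15 lower). These calls were lost with an estimated correlation (adjusted p = 0.440 to 0.524 for endothelial glycolysis, cytokines and disease-associated genes). Myelin genes had a median of −0.19 over 18 members in oligodendrocytes (adjusted p = 0.498 with an estimated correlation) and the endothelial activation genes one of −0.66 over 6 members (adjusted p = 0.513).

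The 3 calls came from 28467 pairs in cortex at 7 d, with 1984 at an unadjusted p under 0.05, and DESeq2 called 9. Camera called 31 of 80 lists and 0 with an estimated correlation. The count was 64 without T4 number 3, 35 without TBI number 3, 24 without TBI number 1 and 8 without TBI number 2. Usp24 was no longer called with DESeq2 (3.73) or without T4 number 2 (2.96) and not tested without T4 number 1. Gria1 lost its call with at least 400 genes per cell (2.01, adjusted p = 0.143), and Adarb2 kept its call under every setting in which it was tested by class. No pair was called when all cells of a library were summed. The T4 effect was larger in cortex than in hippocampus for 2 of 32543 pairs, Gria1 in astrocytes (difference 2.93, SE 0.47, adjusted p = 0.0139) and Adarb2 in excitatory neurons (3.09, SE 0.54, adjusted p = 0.0157), with 1356 at an unadjusted p under 0.05 and 2 by DESeq2. Both differences lost their call without cortex T4 number 1, cortex TBI number 1, or hippocampal T4 number 1 or 2 or TBI number 1 or 3 (2.66 to 2.83 for Gria1, 2.51 to 2.94 for Adarb2). The count was 10 without cortex TBI number 3 and 6 without cortex T4 number 3, and Adarb2's difference was 0.32 at Leiden resolution 2. Both differences lost their call also without the mitochondrial limit (2.36 and 2.50), and Adarb2's with DESeq2 (2.98).

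In hippocampus at 7 d, Usp24 was higher and Darc lower with T4. Usp24 stood at 494 ± 514 CPM with T4 and 38.6 ± 10.4 CPM with TBI in excitatory neurons (log2 fold 3.48, SE 0.52, adjusted p = 0.00364, n = 3 each). Barcodes with under 200 genes held 1733, 278 and 23242 CPM in the T4 libraries and 21.9 to 468 CPM in TBI libraries of 7 d. Darc (Ackr1), the chemokine receptor of venules, stood at 5.47 ± 6.04 and 277 ± 214 CPM in endothelial cells (−5.92, SE 0.78, adjusted p = 0.00976). The list of endothelial activation genes held Darc as Ackr1, a symbol the matrices lack, so it was tested without Darc. The 7 other members had a median of −1.18, all lower, 0 past the threshold and 6 lower when adjusted over the list alone, Lrg1 at −3.84, Il1r1 at −1.40 and Vwf at −1.37 among them. The list's call was lost with an estimated correlation (adjusted p = 0.410). Disease-associated microglia genes had a median of −0.36, 16 of 16 lower (adjusted p = 0.588 with an estimated correlation) and cytokines and chemokines one of −0.29 (adjusted p = 0.605). Apoe in microglia averaged 4927 ± 2932 CPM with T4 and 9733 ± 265 CPM with TBI and was not called (adjusted p = 0.580). Ttr was lower in 10 of 10 classes with a median of −2.10, called in none. Choroid plexus-like cells made up 0.07% to 16.1% of the T4 libraries and 12.3% to 28.5% of the TBI libraries. The 2 calls came from 32214 pairs, with 1795 at an unadjusted p under 0.05, and DESeq2 called 1. Camera called 22 of 86 lists and 0 with an estimated correlation. The count was 24, 24 and 27 without T4 number 1, 2 and 3, and 21, 12 and 5 without TBI number 1, 2 and 3. Darc lost its call with DESeq2 (−5.91, adjusted p = 0.112) and was not tested without TBI number 2. Usp24 lost its call with DESeq2 (3.65, adjusted p = 0.467) and without the mitochondrial limit (3.38, adjusted p = 0.0656).

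The T4 effect in cortex differed between 24 h and 7 d for 13 of 39757 pairs, 8 larger at 24 h and 5 larger at 7 d, 10 of the 13 in endothelial cells. Lcn2, an acute-phase gene, stood at 121 ± 61.9 CPM with T4 and 44.7 ± 22.1 CPM with TBI at 24 h, and at 12.0 ± 15.6 and 331 ± 310 CPM at 7 d (difference of effects 5.89, SE 1.02, adjusted p = 0.0160, n = 3 each). Lrg1 stood at 93.8 ± 42.0 and 25.001 ± 19.0 CPM, then 10.0 ± 12.3 and 323 ± 288 CPM (6.56, SE 1.15, adjusted p = 0.0160). Vwf (2.72, SE 0.47, adjusted p = 0.0160) and Il1r1 (2.34, SE 0.45, adjusted p = 0.0369) differed likewise, and Notum (−2.45, SE 0.45) and Tgfb2 (−1.89, SE 0.35) the other way (adjusted p = 0.0272 for both). At 7 d the high TBI means rested on libraries 2 and 3, with Lcn2 at 334 and 640 CPM against 19.7 CPM in library 1. In astrocytes Gria1 (−3.71, SE 0.58) and the GABA transporter gene Slc6a11 (−2.18, SE 0.35) had T4 effects higher at 7 d (adjusted p = 0.0118 for both), and Usp24 did in oligodendrocytes (−5.68, SE 0.98, adjusted p = 0.0160). The activation genes had a median difference of 2.72, with 4 past the threshold and, adjusted over the list alone, 8 higher and 1 lower. The list's call was lost with an estimated correlation (adjusted p = 0.132).

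These 13 calls had 2801 pairs at an unadjusted p under 0.05 beside them, and DESeq2 called 17. DESeq2 did not call Lcn2 (6.16), Lrg1 (6.88), Vwf (2.73), Il1r1 (2.35), Gria1 (−3.67) or Usp24 (−5.64). At Leiden resolution 2 Lcn2 (4.94), Lrg1 (5.32) and Il1r1 (2.19) lost their calls, and with at least 400 genes per cell Notum (−2.46) and Tgfb2 (−1.92) did. The count was 3 without T4 number 2 of 7 d and 4 without TBI number 3 of 24 h, where Lcn2 (5.39 and 5.56), Lrg1 (6.06 and 6.13), Vwf (2.58 and 2.49), Il1r1 (2.11 and 2.07), Notum (−1.96 and −2.35), Tgfb2 (−1.67 and −1.84) and Usp24 (−3.84 and −5.32) lost their calls. The count was 8 without TBI number 1 of 24 h or T4 number 1 of 7 d, 53 without T4 number 3 of 7 d, 40 and 28 without TBI number 1 and 3 of 7 d, and 28 without T4 number 1 of 24 h. Il1r1 lost its call also without T4 number 2 or 3 or TBI number 2 of 24 h or T4 number 1 or TBI number 3 of 7 d (1.79 to 2.47), Notum without T4 number 1 or 2 or TBI number 1 of 24 h (−2.45 to −2.27). Tgfb2 lost its call also without T4 number 2 or 3 or TBI number 1 of 24 h (−1.96 to −1.72) and Vwf without T4 number 1 of 7 d (2.77). In hippocampus the same difference was called for 0 of 43737 pairs by edgeR (1954 at an unadjusted p under 0.05, DESeq2 0). There were 1 to 16 calls when a library other than T4 number 1 of 24 h was left out, 16 of them without TBI number 1 of 7 d. The activation genes had a median of 1.74 (adjusted p = 0.365 with an estimated correlation).

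At 21 d in hippocampus, transcripts of choroid plexus were higher with T4 in almost every class. Choroid plexus makes cerebrospinal fluid and secretes the thyroid hormone carrier transthyretin, encoded by Ttr. Choroid plexus-like cells made up 7.24% ± 1.21% of cells with T4 (6.66%, 8.63% and 6.43%) and 0.188% ± 0.0363% with TBI (0.205%, 0.214% and 0.147%, exact p = 0.10, n = 3 each). They made up 9.43% in sham library 1 of hippocampus. Over all cells Ttr took 128732, 156809 and 128774 CPM in the T4 libraries, 1039, 1163 and 573 CPM in the TBI libraries and 216376 CPM in that sham library. Ttr was higher in 12 of 12 classes outside the choroid plexus and called in 11 (median log2 fold 7.65, 3.69 to 8.15), as in astrocytes with 6542 ± 883 against 33.4 ± 5.85 CPM (7.62, SE 0.20). Enpp2, the other abundant choroid transcript, was called in astrocytes (343 ± 64.9 against 42.4 ± 5.79 CPM, 3.06, SE 0.19), microglia (3.01), mural cells (2.98), endothelial cells (2.75), excitatory neurons (2.71) and oligodendrocyte precursors (0.78). 1500015O10Rik was called in oligodendrocytes (6.12), excitatory neurons (4.66), endothelial cells (4.50) and astrocytes (2.34). Otx2 was listed at 0 counts in TBI oligodendrocytes and at 9.13 ± 0.42 CPM with T4. The choroid plexus list passed with an estimated correlation in oligodendrocytes (median 3.58, 9 of 11 members past the threshold, adjusted p = 0.00567), excitatory neurons (2.94, adjusted p = 0.00498), endothelial cells (2.75, adjusted p = 0.00993) and astrocytes (2.60, adjusted p = 0.00498).

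**Figure D3:**
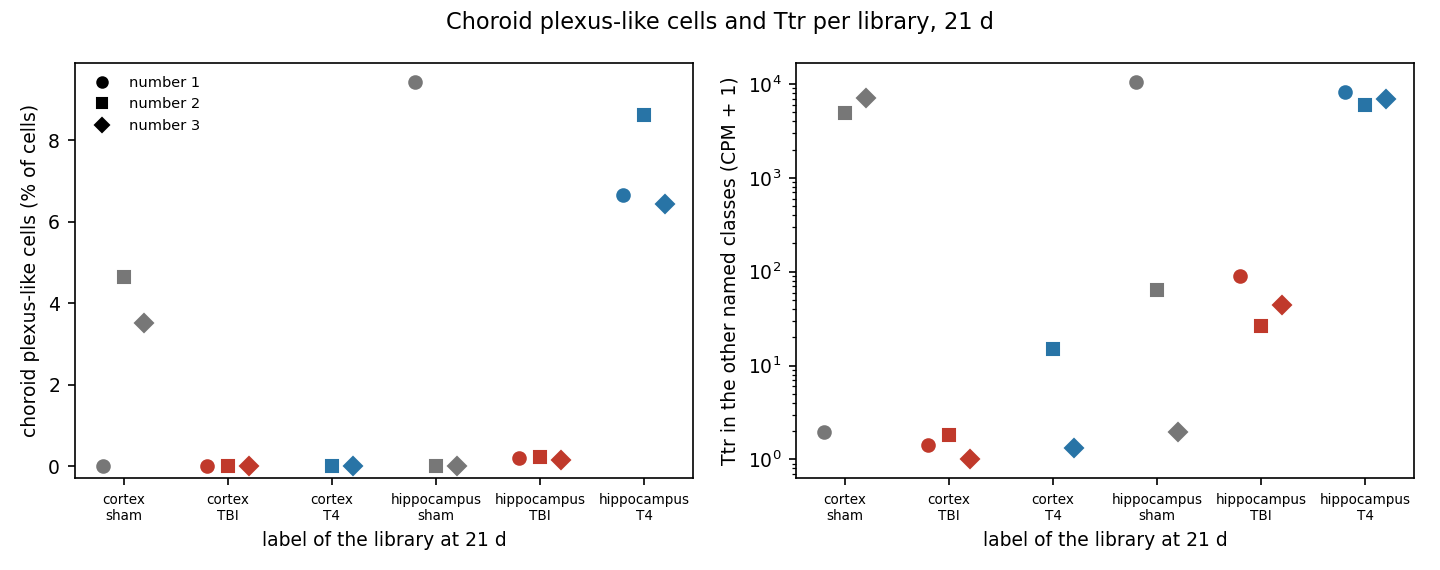
Share of choroid plexus-like cells (left) and Ttr in the other named classes (right) per library at 21 d. Sham libraries are placed under their labelled tissue.

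Of the 50 called pairs in hippocampus at 21 d, 45 were higher and 5 lower with T4. Cldn11, a claudin gene of myelin, was lower in excitatory neurons (log2 fold −1.71, SE 0.27, adjusted p = 0.0106, n = 3 each), and mt-Tv and Kif5a were lower in astrocytes (−0.92, SE 0.17, for both, adjusted p = 0.0316 and 0.0336). Thyroid hormone responsive genes had a median of −0.33 in excitatory neurons, with 12 of 13 members lower and 4 lower when adjusted over the list alone (adjusted p = 0.0881 with an estimated correlation). Among thyroid hormone transport, conversion and receptor genes Ttr was the only member called. The list was not tested without Ttr, but its mean lay well above its median. In oligodendrocyte precursors, astrocytes and excitatory neurons the list's median was 0.06, 0.05 and 0.07 and its mean 0.73, 0.61 and 0.77 (adjusted p = 0.0229, 0.0425 and 0.0425 with an estimated correlation). In oligodendrocytes and endothelial cells the median was −0.16 and −0.12 against means of 0.73 and 0.64, called upward at the preset correlation (adjusted p = 0.0671 and 0.139 with an estimated correlation). Synaptic genes had a median of −0.18 in excitatory neurons (adjusted p = 0.779 with an estimated correlation) and Gfap in astrocytes a fold of 0.03 (SE 0.21). The 50 calls came from 62179 pairs, with 3684 at an unadjusted p under 0.05, and DESeq2 called 59. Camera called 28 of 116 lists, 7 of them with an estimated correlation. T4 number 1, tagged TBI in its characteristic, gave 0 calls when counted as TBI, and without the choroid-enriched genes 22 were left. The genes left out did not include 1500015O10Rik or Otx2, so choroid plexus transcripts remained among the 22. Cldn11 lost its call without TBI number 1 (−1.74) or T4 number 1 (−1.78), and when doublets were left out (−1.50). mt-Tv and Kif5a lost theirs without TBI number 1 (−0.82 and −0.81), TBI number 3 (−0.94 and −0.91) or T4 number 2 (−0.79 and −0.81), and mt-Tv also without TBI number 2 (−0.999) or with at least 400 genes per cell (−0.89). Kif5a lost its call also without the mitochondrial limit (−0.72) and at Leiden resolution 2 (−0.85), and both did without the choroid-enriched genes (−0.92 for both). With spread shared by 3 groups Cldn11, mt-Tv and Kif5a were not called (−1.73, −0.92 and −0.92). Ttr was not called then in 7 classes (5.70 to 8.14), nor 1500015O10Rik in astrocytes (2.35), endothelial cells (4.49) and excitatory neurons (4.62). Enpp2 in precursors lost its call without T4 number 3 (0.66), TBI number 1 (0.74) or TBI number 3 (0.76), and Otx2 without TBI number 1.

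Cortex at 21 d, with 2 T4 and 3 TBI libraries, had no called pair. Dio2, the deiodinase that activates T4, averaged 399 ± 27.5 CPM with T4 and 452 ± 101 CPM with TBI in astrocytes (log2 fold −0.23, SE 0.22, adjusted p = 1.00), and Hr, a direct thyroid hormone target, 15.1 ± 1.32 and 7.95 ± 5.81 CPM in oligodendrocytes (0.89, SE 0.64). Thyroid hormone responsive genes had a median of −0.27 in excitatory neurons and immediate early genes one of 0.72 in astrocytes, called only at the preset correlation (lowest adjusted p = 0.892 over all lists with an estimated correlation). edgeR called 0 of 58507 pairs, with 1349 at an unadjusted p under 0.05, and DESeq2 called 2. Camera called 15 of 98 lists and 0 with an estimated correlation. Without TBI number 2 the count of pairs was 1. The T4 effect was smaller in cortex than in hippocampus for Enpp2 in astrocytes (difference −3.45, SE 0.37, adjusted p = 0.00197) and endothelial cells (−3.07, SE 0.38, adjusted p = 0.0451), 2 of 65699 pairs, with 3077 at an unadjusted p under 0.05 and 9 by DESeq2. Without cortex T4 number 3 neither was called (−3.21 and −2.85), nor with group and number as a block (−3.38, SE 0.39, and −2.93, SE 0.32). The endothelial one was lost also with at least 400 genes per cell (−2.80), without cortex T4 number 2 or TBI number 2 or any 1 hippocampal library (−3.38 to −2.93), and the count was 3 without cortex TBI number 1 and 7 without cortex TBI number 3.

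Injury alone was read at 21 d, first with both tissues summed per number. Ttr was lower with TBI than with sham in 12 of 12 classes outside the choroid plexus and called in each (median log2 fold −7.21, −7.76 to −3.50), as in excitatory neurons with 19.7 ± 1.76 against 3672 ± 820 CPM (n = 3 each). Choroid plexus-like cells made up 0.0933% ± 0.0136% against 2.71% ± 0.812% of cells (exact p = 0.10). Enpp2 in astrocytes (−1.94) and excitatory neurons (−1.34) and 1500015O10Rik in 6 classes were lower too. Kif5a, a kinesin of axonal transport, was higher with TBI in astrocytes (204 ± 30.8 against 76.5 ± 8.15 CPM, 1.49, SE 0.16, adjusted p = 0.00138), as were mt-Te in astrocytes (1.05, SE 0.15, adjusted p = 0.0197) and Rims3 in excitatory neurons (1.66, SE 0.28, adjusted p = 0.0404). Apoe in microglia stood at 2396 ± 894 and 1104 ± 461 CPM (1.15, SE 0.25, adjusted p = 0.305), and Gfap in astrocytes at 287 ± 35.6 and 206 ± 85.8 CPM (0.55, SE 0.25, adjusted p = 0.990), neither called. The choroid plexus list kept its call with an estimated correlation in oligodendrocytes (median −3.55, 4 of 9 members past the threshold and 7 adjusted over the list alone, adjusted p = 0.00238), excitatory neurons (−1.34, adjusted p = 0.00397), astrocytes (−1.69, adjusted p = 0.00826) and precursors (−0.43, adjusted p = 0.0135). The transport list, led by Ttr, kept its call in 5 classes with medians of −0.38 to −0.09 (adjusted p = 0.00826 to 0.0471), while in precursors a median of 0.08 stood against a mean of −0.44 and a downward test (adjusted p = 0.0623). Cytokines and chemokines (0.32, 3 members adjusted over the list alone), disease-associated genes (0.24) and cholesterol synthesis in oligodendrocytes (0.24) were called upward only at the preset correlation (adjusted p = 0.567, 0.759 and 0.366 with an estimated correlation).

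This comparison called 31 of 86290 pairs, 3 higher and 28 lower, with 4347 at an unadjusted p under 0.05, and DESeq2 called 80. Camera called 41 of 127 lists, 9 with an estimated correlation. The count was 59 without sham number 2. Without the choroid-enriched genes 11 pairs were called, and with tissue as a covariate 1. The genes left out did not include 1500015O10Rik, which remained among the 11. Kif5a lost its call with the covariate (1.29), without the mitochondrial limit (1.01) or without the 2 libraries with shorter gene lists (1.47). mt-Te lost its call without TBI number 1, 2 or 3 (0.94, 1.13 and 1.08) or sham number 1 (0.99), and without the mitochondrial limit (0.83) or the 2 libraries with shorter gene lists (0.98). It was lost also with the covariate (0.64, and 0.69 with the sham tissues exchanged) and with the number as a block (1.05). Rims3 lost its call without TBI number 1, 2 or 3 (1.59, 1.61 and 1.73) or sham number 2 (1.25), and without the 2 libraries with shorter gene lists (1.68) or the choroid-enriched genes (1.66). It was lost also with the covariate (1.68, and 1.61 with the sham tissues exchanged), with the number as a block (1.63) and at Leiden resolution 2 (1.63). Enpp2 lost its call with the covariate in astrocytes (−2.04, and −1.91 with the sham tissues exchanged) and excitatory neurons (−1.14 and −1.10), in astrocytes also without the 2 libraries with shorter gene lists (−1.97) and in excitatory neurons at Leiden resolution 2 (−1.01). With the covariate Ttr, tested in 6 classes, lost its call in astrocytes (−7.86), oligodendrocytes (−8.21), endothelial cells (−8.26), microglia (−6.71) and fibroblast-like cells (−0.21) and turned to 9.48 in ependymal cells. With the sham tissues exchanged as well, it lost its call in microglia (−5.94) and ependymal cells (−3.86) alone. In ependymal cells it was lost also with DESeq2 (−3.59), and with spread shared by 3 groups (−3.52). Ttr lost its call in inhibitory neurons with at least 400 genes per cell (−6.51), when adjusted within each class, without the 2 libraries with shorter gene lists (−6.01), and without TBI number 1, 2 or 3 (−6.88, −5.87 and −8.28) or sham number 1 (−7.02), and 1500015O10Rik in excitatory neurons without TBI number 1 or 2 (−3.55 and −4.05) or sham number 1 (−3.89) and in microglia without TBI number 2 or 3 (−4.25 and −4.50) or sham number 3 (−4.46) or with the number as a block (−4.86). Without the 2 libraries with shorter gene lists it lost its call in excitatory neurons (−3.49), microglia (−7.01) and astrocytes (−1.96), and in astrocytes also with the covariate (−2.22, and −2.36 with the sham tissues exchanged).

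By labelled tissue, TBI against sham called 71 of 55843 pairs in hippocampus and 0 of 56463 in cortex. In the hippocampus as labelled, astrocytes had more mt-Tv and mt-Ta with TBI (log2 folds 3.41 and 2.68), oligodendrocytes less Sgk1, a kinase induced by glucocorticoid (−1.87), and these 3 kept their calls whichever library was left out. Immature neurons, read in n = 2 libraries each, had more Neurod1 (839 ± 277 CPM against 1 UMI in all) and less Nrxn3 with TBI (107 ± 91.0 against 1784 ± 586 CPM, −4.40), where sham was libraries 2 and 3, the ones in doubt. With the sham tissues exchanged mt-Tv stood at 0.80, mt-Ta at 0.60, Sgk1 at −1.96 and Neurod1 at 0.78, none of them called. Ttr in oligodendrocytes was lower with TBI (−6.88, SE 1.37, adjusted p = 0.0416), but sham libraries ranged from 2.24 to 9653 CPM, and without sham number 1 the fold was 2.48. It lost its call also at Leiden resolution 2, with at least 50 cells of a class, when adjusted within each class, with spread shared by 3 groups (−6.88 to −6.87) and without any 1 TBI library. With the number as a block it was not called (−3.47, adjusted p = 0.578), while Apoe in microglia was (1.29). Gfap was 1.19 (SE 0.30, adjusted p = 0.225) in hippocampus and −1.41 (SE 0.54, adjusted p = 1.00) in cortex as labelled, not called. Reactive astrocyte genes had a median of 0.68 over 8 members (5 adjusted over the list alone) and disease-associated microglia genes one of 0.34, 14 of 15 higher, in hippocampus as labelled (adjusted p = 0.444 and 0.818 with an estimated correlation). The unadjusted p was under 0.05 for 4401 pairs in hippocampus and 1855 in cortex, and DESeq2 called 105 and 24. Camera called 29 of 97 lists in hippocampus and 24 of 97 in cortex, 0 with an estimated correlation. The hippocampal count was 316 without sham number 1, 17 without sham number 3, 19 without TBI number 1, 18 without TBI number 3 and 20 with the sham tissues exchanged. The cortical count was 14 without sham number 1.

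T4 against sham, with both tissues summed, left Ttr near its sham level, with a median log2 fold of −0.14 over 13 classes (−0.40 to 0.41, none called; n = 2 and 3). The haemoglobin genes Hba-a2 and Hbb-bt, which red cells bring, were higher with T4 in microglia (1401 ± 287 against 263 ± 91.7 CPM for Hba-a2, 2.43, SE 0.22, adjusted p = 4.28e-05, and 2.20 for Hbb-bt). Rpl23a, a ribosomal protein gene, was lower in precursors (−1.35, adjusted p = 0.00904), oligodendrocytes (−1.37, adjusted p = 0.0213) and endothelial cells (−1.33, adjusted p = 0.0407). Apoe in microglia (0.59, SE 0.21) and Dio2 in astrocytes (−0.73, SE 0.27) were not called. edgeR called 7 of 99277 pairs, 4 higher and 3 lower, with 4733 at an unadjusted p under 0.05, and DESeq2 called 45. Camera called 30 of 142 lists and 0 with an estimated correlation (lowest adjusted p = 0.737). The count was 26 without T4 number 2, 13 without T4 number 3, and 15 without sham number 2 or 3. Rpl23a lost its calls in the 3 classes without sham number 1 (−1.35 to −1.30) or T4 number 3 (−1.45 to −1.16), and in precursors without T4 number 2 (−1.25). In endothelial cells it was lost also with at least 400 genes per cell (−1.35).

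To ask whether T4 moved genes against the direction of injury, folds of T4 against TBI were correlated with those of TBI against sham at 21 d. The median correlation over 12 classes was −0.426 (−0.785 to −0.389), and sharing the TBI libraries alone gave −0.441 (SD 0.00591) over 20 simulated groups without any change. In excitatory neurons the correlation was −0.534 against −0.443 in the simulation, with a covariance of −0.0696 against −0.0454, and in inhibitory neurons it was −0.405 against −0.465. Fibroblast-like cells, read in 2 TBI sums, stood apart with −0.785 against −0.498 and a covariance of −0.487 against −0.128. Genes are not independent of each other, so no p was attached. The median moved to between −0.559 and −0.339 when 1 sum was left out, to −0.385 without the choroid-enriched genes and to −0.468 without the 2 libraries with shorter gene lists. The simulation was not repeated for these settings. Leaving out a sum also changes what sharing the TBI libraries alone gives, so these values cannot be set beside −0.441.

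**Figure D4:**
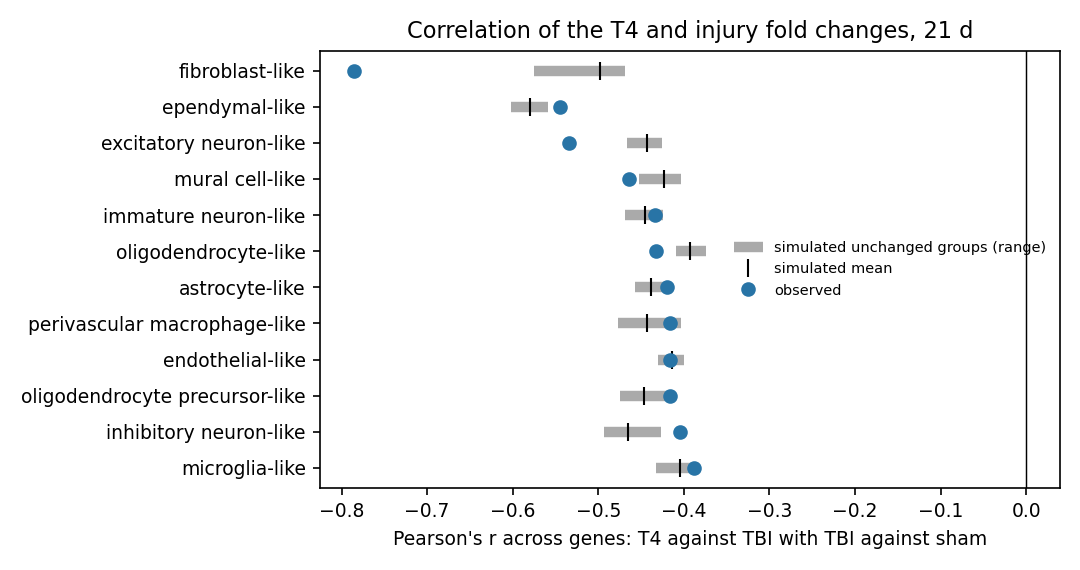
Correlation per class between the T4 effect and the injury effect at 21 d, beside the mean and range that shared TBI libraries give in simulated groups without change.

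Shares of classes among the cells recovered after papain and the density gradient were compared by exact permutation. In cortex at 24 h inhibitory neurons made up 4.63% ± 3.64% with T4 and 21.4% ± 7.69% with TBI, immature neurons 2.83% ± 1.85% and 5.83% ± 0.488%, and endothelial cells 16.8% ± 3.35% and 13.01% ± 1.43%. With astrocytes (16.0% ± 3.52% and 12.0% ± 0.932%), oligodendrocytes (15.4% ± 2.16% and 10.995% ± 1.77%) and precursors (9.04% ± 0.6998% and 6.59% ± 1.15%), 6 of 14 classes did not overlap between groups. Chance gives 10% (exact p = 0.10 each, the smallest possible, adjusted p = 0.233, n = 3 each). Shares sum to 100%, so these classes are not independent, and fewer inhibitory neurons raise every other share. Among the cells other than inhibitory neurons, 2 of 13 classes were without overlap, immature neurons (3.00% and 7.44%) and fibroblast-like cells (0.542% and 0.713%), while endothelial cells made up 17.6% and 16.5%. With at least 400 genes per cell 3 classes were without overlap. At 24 h inhibitory neurons were mostly of cluster 10 (led by Cpne6, Gad1 and Meis2) in both cortex groups and of cluster 7 (led by Calb2 and Gad2) in both hippocampal groups. In hippocampus at 24 h astrocytes (15.2% and 10.3%), microglia (10.4% and 8.57%) and oligodendrocytes (16.6% and 22.9%) did not overlap (3 of 14, adjusted p = 0.467). At 7 d endothelial cells made up 16.0% ± 2.34% with T4 and 9.01% ± 0.419% with TBI in hippocampus, and astrocytes 6.44% and 9.93% (3 of 14 without overlap, exact p = 0.10, adjusted p = 0.467), with oligodendrocytes mostly of cluster 9 with T4 and of cluster 16 with TBI. In cortex astrocytes alone were without overlap (9.37% and 12.8%, 1 of 14). At 21 d in hippocampus endothelial cells (13.9% ± 0.512% and 17.6% ± 0.747%) and ependymal cells (1.35% and 0.708%) were without overlap beside the choroid plexus-like cells (3 of 14). In cortex ependymal cells (0.773% and 0.167%) and excitatory neurons (5.32% and 2.79%) were (2 of 13, exact p = 0.20). TBI against sham had 2 of 14 in both tissues (choroid plexus-like cells and oligodendrocytes, 24.9% ± 0.856% and 18.3% ± 3.81%). It had 3 of 14 in cortex as labelled, among them astrocytes (9.40% and 15.0%), and 0 of 14 in hippocampus as labelled. At 21 d inhibitory neurons of TBI cortex and of sham hippocampus as labelled were mostly of cluster 16 (led by Calb2), and those of sham cortex as labelled and of the T4 and TBI hippocampus of cluster 2 (led by Sst).

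Klf9, which thyroid hormone induces through its receptor, was not called in any class or comparison. Its median log2 fold, T4 against TBI, was −0.01 over 7 classes in cortex and 0.25 over 8 in hippocampus at 24 h, 0.19 and 0.12 at 7 d, and 0.07 and −0.32 at 21 d. Mbp in oligodendrocytes, a myelin gene that thyroid hormone controls in development, had folds of −0.10 and −0.07 at 24 h, 0.00 and −0.16 at 7 d and −0.09 and 0.07 at 21 d in cortex and hippocampus. The mitochondrial ribosomal RNA mt-Rnr2 had medians of 0.29 and 0.65 at 24 h, −0.10 and 0.19 at 7 d and −0.83 and 0.37 at 21 d, not called in any class.

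Gene lists were tested in up to 148 combinations of class and comparison each. Thyroid hormone responsive genes were called in 11 of 109 and thyroid hormone transport, conversion and receptor genes in 18 of 112, mitochondrially encoded transcripts in 53 of 148, oxidative phosphorylation genes in 65 of 146, glycolysis in 24 of 131, ribosomal proteins in 50 of 148, immediate early and stress genes in 38 of 148, antioxidant genes in 8 of 142, cholesterol synthesis in 16 of 85, interferon-stimulated genes in 25 of 111 and choroid plexus transcripts in 20 of 34. Of the lists read in 1 class, disease-associated microglia genes, cytokines and reactive astrocyte genes were called in 6 of 15 each, endothelial activation genes in 8 of 15, blood-brain barrier genes in 5 of 15, astrocyte handling of glutamate, water and potassium in 4 of 15, homeostatic microglia and myelin genes in 1 of 15 each, and synaptic genes in 2 of 25. With an estimated correlation 8 calls of the transport list and 8 of the choroid plexus list held, and 0 of any other list. Haemoglobin genes never had 5 tested members and were not tested as a list.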

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

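The 8 tests of the 3 patterns weighed first were chosen only after the result was seen, while the counts over other splits of the libraries were planned before it.

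Choroid plexus transcripts were higher with T4 than with TBI in nearly every hippocampal class at 21 d, and lower with TBI than with sham. RNA released by choroid plexus cells of the same library would hold 1 ratio of its genes in every class. The ratio was read in 6 T4 and sham libraries with many choroid plexus-like cells, where at least 10 UMIs of 1500015O10Rik could be awaited. 1500015O10Rik relative to Ttr lay within 2-fold of its ratio in barcodes under 200 genes in 100% of 39 library and class sums (0.00478 to 0.0199, against 0.00886 to 0.0100). That source would give this for the classes outside the choroid plexus, but TBI libraries were not covered. In the choroid plexus-like cells of these libraries the ratio was much the same (0.00922 to 0.0134). The ratio therefore cannot tell released RNA from choroid plexus cells counted in other classes, alone or in doublets. A rise of Ttr alone is excluded, since 21 other pairs of 10 genes of the choroid plexus list were called higher as well. Whether the tissue pieces held more choroid plexus or the plexus had more cells stays open: within 1 group of hippocampal libraries, T4 at 7 d, the share of choroid plexus-like cells already differed 230-fold (0.07% to 16.1%), but the shares of the 21 d groups do not overlap, and dissection cannot be told apart from treatment there. The split of libraries into T4 and TBI gave 50 calls against 26 in the highest other split (1 of 10 splits reached 50), and that into TBI and sham with both tissues summed 31 against 14 (1 of 10), with too few splits for a share under 0.05.

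The tissue of sham libraries 2 and 3 at 21 d sided with their file names. With genes chosen at 24 h and 7 d, 4 of 4 libraries lay on the side of the other tissue, while 13 of 13 other libraries of 21 d lay on their own, which is what exchanged tissue labels would give. Choroid plexus carried along with cortex pieces would leave the score among cortex libraries once choroid-enriched genes are out, yet the lower score of the libraries labelled cortex was 0.566, above the −1.32 of the highest other cortex library. The expression thus stands against the labels of these 4 libraries and with their file names, and at which step the tissues were exchanged was not tested. Of the splits of hippocampus as labelled, 1 that set sham 2, sham 3 and TBI 2 apart gave 193 calls against the real 71 (2 of 10 splits reached 71), which points to a structure of the samples other than injury.

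Endothelial activation genes had a median log2 fold of 1.50, T4 against TBI, in cortex at 24 h. A larger share of venous cells would raise venous markers, whose median was −0.0811 (SE 0.264) over 3 genes. Nr2f2 was higher (0.36), Slc38a5 (−0.25) and Flt4 (−0.08) lower. Darc, the receptor gene of venules, stood at 14.0, 157 and 33.7 CPM with T4 and 20.8, 10.6 and 0 CPM with TBI. So few and divided markers cannot decide the share of venous cells. Stress of dissociation would raise the immediate early and stress genes, whose median was 0.10 (SD 0.19) over 21 genes, 15 of them above 0. This argues against such stress. The 5 arterial markers were all lower with T4 (Gkn3 −1.55, SE 0.33, adjusted p = 0.108, Efnb2 −0.52, Sema3g −0.36, Bmx −0.34 and Hey1 −0.03), none called, so a smaller share of arterial cells stays open. An effect of T4 on endothelium at 24 h may be considered as a hypothesis, with a median of at least 1.17 whichever library was left out. But a difference in blood or injury between the mice of the groups was not tested, and the list lost its call with an estimated correlation. The tissue score, whose genes were chosen partly in these libraries, also differed. It was −2.11, −2.42 and −1.38 with T4 and −2.92, −2.77 and −2.84 with TBI. Inhibitory neurons numbered 423 with T4 and 2044 with TBI. A difference in the tissue pieces taken was not tested either, and cannot be told apart from treatment here. The real split gave 5 calls, 3 of 10 splits reached that and the highest other gave 25, too few splits for a share under 0.05.

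Among differences of the T4 effect between 24 h and 7 d in cortex, the endothelial genes Lcn2 (5.89), Lrg1 (6.56), Vwf (2.72), Il1r1 (2.34), Notum (−2.45) and Tgfb2 (−1.89) passed the threshold. The same difference passed for Gria1 (−3.71) and Slc6a11 (−2.18) in astrocytes and Usp24 (−5.68) in oligodendrocytes. The 13 calls were reached by 1 of 25 splits, the real one, with 8 in the highest other, a share under 0.05. It is the smallest share that 25 splits can give, and no other count over splits fell under 0.05. Chance is therefore not excluded by this 1 result, and 3 calls were left without T4 number 2 of 7 d. Between tissues at 7 d, the T4 effect differed for Gria1 in astrocytes (2.93) and Adarb2 in excitatory neurons (3.09), where 8 of 24 splits gave at least the 2 calls and 1 gave 22, so chance cannot be excluded. Between tissues at 21 d, it differed for Enpp2 in astrocytes (−3.45) and endothelial cells (−3.07), a choroid plexus transcript whose level followed the choroid plexus-like cells of hippocampus, but with group and number as a block neither was called (−3.38 and −2.93). Usp24 reached 23242 CPM in barcodes with under 200 genes of hippocampal T4 library 3 at 7 d, where the highest TBI library of 7 d had 468 CPM.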

How the results depend on the processing

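Alternatives were fixed before the data were examined except for leaving out the 2 libraries with shorter gene lists, leaving out the choroid-enriched genes, tissue as a covariate with the sham tissues exchanged, the block for the tissue differences, and shares in cortex at 24 h without inhibitory neurons, which were chosen after the data had been seen. Of 109 called gene and class pairs that were named, 17 stayed past the threshold under every setting in which they were tested. Most were Ttr or 1500015O10Rik in classes outside the choroid plexus. Hba-a2 and Hbb-bt in microglia, and Dlx6os1 and Nrxn3 in immature neurons of hippocampus as labelled, were others. The last 2 were tested in 11 settings each. Their sham cells came from libraries 2 and 3, whose tissue is in doubt, and Dlx6os1 was a cortical gene of the tissue score (−3.27, hippocampus against cortex). These 2 calls therefore cannot be told apart from a difference of tissue, although they were kept. The rest were Akap12 and Vwf in endothelial cells of cortex at 24 h, Adarb2 in excitatory neurons of cortex at 7 d, and the time difference of Slc6a11 in astrocytes of cortex. Over all settings these pairs kept direction and call 1605 times, lost the call 380 times and reversed 3 times. List results named from camera did so 1331, 448 and 4 times. Except where a reason is given, the cause was not tested.

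DESeq2's Wald test called 30 pairs for T4 against TBI in cortex at 24 h, 5 in hippocampus at 24 h, 9 in cortex and 1 in hippocampus at 7 d, and 2 in cortex at 21 d. It called 80 for TBI against sham with both tissues, 24 in cortex as labelled, 45 for T4 against sham and 9 for the tissue difference at 21 d. With DESeq2's size factors in edgeR, cortex at 24 h had 17 calls.

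Without the low-count filter, genes with as few as 1 count entered by construction and each of the 15 counts was higher. T4 against TBI had 158 calls in cortex and 207 in hippocampus at 24 h, 111 and 89 at 7 d, and 158 and 408 at 21 d. TBI against sham had 515 with both tissues, 201 in cortex and 707 in hippocampus as labelled, and T4 against sham had 314. The tissue differences had 72 at 24 h, 19 at 7 d and 330 at 21 d, and the time differences 164 in cortex and 93 in hippocampus.

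Adjustment within each class gave 34 calls in cortex and 4 in hippocampus at 24 h, 5 and 7 at 7 d, 30 for the time difference in cortex and 1 in hippocampus, 1 for the tissue difference at 24 h, and 2 in cortex and 120 in hippocampus as labelled for TBI against sham. Here the family of tests shrank by construction.

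Summing all cells of a library left 0 calls for T4 against TBI in cortex at 24 h and at 7 d and in hippocampus at 7 d, 0 for T4 against sham, 0 for TBI against sham in hippocampus as labelled and 0 for the tissue difference at 7 d, and 3 for the time difference in cortex. In hippocampus at 21 d the sums gave 2249 calls, for the tissue difference at 21 d 221 and for TBI against sham with both tissues 216, where choroid plexus-like cells entered the sums.

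With the replicate number as a block, T4 against TBI had 58 calls in cortex and 1 in hippocampus at 24 h, 30 and 9 at 7 d, and 44 in cortex at 21 d, and T4 against sham had 42. The blocked count was 64 in hippocampus at 21 d, and for TBI against sham 54 in hippocampus as labelled, 24 with both tissues and 0 in cortex. For the tissue differences the block was the group and number shared by the 2 tissues, and 6 pairs were called at 24 h (from 0), 2 at 7 d and 0 at 21 d (from 2, Enpp2 at −3.38 in astrocytes and −2.93 in endothelial cells), with 22, 16 and 16 lists called. Each T4 library of cortex at 24 h correlated best with the hippocampal library of its own number, and each sham library labelled hippocampus at 21 d with the TBI library of its own number. Only these 2 of 17 pairs of groups had 3 same-numbered correlations all above 0.1, and sham 2 and 3 labelled hippocampus scored as cortex. These correlations therefore do not decide what a number marks. The list result "cytosolic ribosomal proteins, ependymal, T4 against TBI, hippocampus 21 d" had a median of −0.10 with the block, from 0.40.

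Cell filters moved the smaller counts. At least 400 genes per cell gave 10 calls in cortex at 24 h, 6 in hippocampus at 7 d and 1 for the tissue difference at 21 d, and 3 classes without overlap of shares in cortex at 24 h (from 6) and 6 in hippocampus at 7 d (from 3). Among cells other than inhibitory neurons 2 classes in cortex at 24 h were without overlap. Without the mitochondrial limit there were 16 calls in cortex at 24 h, 1 in hippocampus at 7 d and 0 for the tissue difference at 7 d. With doublets left out there were 16 and 4 calls in cortex at 24 h and hippocampus at 7 d, and the median correlation of T4 and injury effects was −0.436. At Leiden resolution 2 there were 7 calls in hippocampus at 7 d, 1 for the tissue difference at 7 d and 36 for TBI against sham in hippocampus as labelled, and the correlation was −0.417. With at least 50 cells of a class the last count was 30, from fewer classes.

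Groups and genes at 21 d mattered as well. With spread shared by 3 groups hippocampus had 23 calls for T4 against TBI, with T4 number 1 counted as TBI it had 0, and without the choroid-enriched genes it had 22. Without those genes TBI against sham with both tissues had 11 calls, the tissue difference 0, and the correlation of T4 and injury effects was −0.385. Fewer genes were tested there by construction. 1500015O10Rik and Otx2 were not left out, so choroid plexus transcripts stayed among the 22 and 11 calls. With tissue as a covariate TBI against sham had 1 call, and with the sham tissues exchanged as well 6; Tgfbi in fibroblast-like cells turned to 1.79 and Ttr in ependymal cells to 9.48, from −2.69 and −3.50. With the sham tissues exchanged, hippocampus had 20 calls and the list result "interferon-stimulated genes, oligodendrocyte, TBI against sham, cortex 21 d as labelled" turned to 0.10, from −0.41. Without the 2 libraries with shorter gene lists T4 against sham had 15 calls, TBI against sham in cortex 1, and the correlation was −0.468.

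With an estimated correlation between genes, camera called 7 lists in hippocampus at 21 d and 9 for TBI against sham with both tissues, and 0 in each of the other 13 comparisons. The simulated list that had been shifted was called at the preset correlation in every comparison, and at the estimated one in the tissue difference at 7 d alone (adjusted p = 0.0293). Genes were drawn independently of each other in these simulations. They therefore cannot show whether the preset correlation holds in the real libraries.

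Leaving out 1 library at a time gave 5 to 144 calls in cortex at 24 h (144 without T4 1), 0 to 46 in hippocampus at 24 h (46 without TBI 2), 3 to 64 in cortex at 7 d (64 without T4 3), 5 to 27 in hippocampus at 7 d (27 without T4 3) and 0 to 1 in cortex at 21 d. For TBI against sham it gave 0 to 14 in cortex (14 without sham 1), 17 to 316 in hippocampus (17 without sham 3, 316 without sham 1) and 21 to 59 with both tissues (59 without sham 2), and for T4 against sham 5 to 26 (26 without T4 2). The tissue differences ranged over 0 to 5, 0 to 10 and 0 to 7 at 24 h, 7 d and 21 d, and the time differences over 3 to 53 in cortex and 0 to 16 in hippocampus. Lists called ranged over 17 to 35 in cortex at 7 d, 6 to 33 in cortex at 21 d, 15 to 41 and 18 to 40 for TBI against sham in cortex and hippocampus as labelled, 11 to 29, 12 to 24 and 12 to 33 for the tissue differences, and 14 to 25 for the time difference in cortex. Ttr in oligodendrocytes of hippocampus as labelled ran from −7.48 to 2.48 (2.48 without sham 1), the ribosomal list in ependymal cells at 21 d from −0.10 to 0.59, and the immediate early list in astrocytes of hippocampus as labelled from −0.84 to −0.10, where the test turned direction without TBI 2. The correlation of T4 and injury effects ranged over −0.559 to −0.339 when 1 sum was left out, with no simulation repeated beside it.

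In simulated data the comparisons of 3 against 3 libraries recovered at most 40.0% of genes changed 2-fold, and cortex at 21 d with 2 against 3 recovered 1.06%. Depth was not varied in these simulations.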

Other observations

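The counts over other splits were planned before the result was seen, and the relation between inhibitory neurons and astrocyte genes was looked for after it.

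Other splits of the same libraries were fitted for the remaining counts of calls. With 10 splits, too few for a share under 0.05, cortex at 7 d had 3 calls (6 of 10 splits reached that, highest other 49) and hippocampus at 7 d 2 (8 of 10, highest other 13). Hippocampus at 24 h (10 of 10 splits, highest other 24), TBI against sham in cortex as labelled (10 of 10, highest other 0), the tissue difference at 24 h (23 of 23, highest other 11) and the time difference in hippocampus (25 of 25, highest other 13) had 0 calls, which every split reaches, so these splits test nothing. In hippocampus at 24 h the split with 24 calls set T4 1, T4 3 and TBI 2 apart, and in cortex at 7 d that with 49 set T4 1, T4 2 and TBI 3 apart, several times the real counts, which points to a structure of the samples that the groups do not describe.

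For lists called by camera, 10 splits are again too few for a share under 0.05. T4 against TBI had 20 lists in cortex at 24 h (6 splits reached that, highest other 27), 23 in hippocampus at 24 h (6, highest other 36), 31 in cortex at 7 d (1, highest other 25), 22 in hippocampus at 7 d (4, highest other 29) and 28 in hippocampus at 21 d (6, highest other 39). TBI against sham had 24 in cortex as labelled (4, highest other 34), 29 in hippocampus as labelled (4, highest other 41) and 41 with both tissues (1, highest other 35). Chance cannot be excluded for the 16 lists of the tissue difference at 24 h (19 of 23 splits, highest other 30), the 14 at 7 d (12 of 24, highest other 25), and the 23 and 24 of the time differences in cortex (9 of 25, highest other 37) and hippocampus (7 of 25, highest other 33).

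Inhibitory neurons made up 35.8% of cells in the library labelled hippocampal sham 2 at 21 d, with Calb2 at 637 CPM over all cells, and 15.4% in cortex TBI library 2 at 21 d, with Calb2 at 239 CPM. Calb2 marks a subset of inhibitory neurons. In cortex at 24 h the TBI libraries held 16.4% to 30.3% inhibitory neurons and the T4 libraries 1.06% to 8.33%, and Islr was higher in TBI astrocytes of that group. No test linked these values.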
